A study of Arabidopsis thaliana with 21 samples.

How the data were processed

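Total RNA of Arabidopsis thaliana T87 cells, a suspension cell line of the Col-0 ecotype, was biotin-labelled and hybridised to Affymetrix GeneChips, per the labels' protocols. The 21 arrays fell into 7 groups of 3 arrays each, taken from the sample titles: cells kept at 22°C and collected 0, 1 and 3 h after addition of cordycepin, and cells held at 4°C for 24 h and collected 0, 1, 3 and 6 h after addition of cordycepin. Control cells were used 7 days after subculture under light of 80 µmol per square metre and second, and the cold-treated cells stood in dimmer light of 40 µmol per square metre and second, so temperature and light differ together. The labels number the replicates of each time point but do not say that they came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

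The deposited values were linear probe set intensities, 1 column per array, and RMA and the affy package are named for them, per the submitters' processing notes, with no version or order of steps. The basis of the overall level of each array is not given in the sources used here, nor is any centring of the arrays. The median of the log2 intensity of single arrays lay between 4.94 and 6.93, and it was lowest on the arrays taken 3 h after cordycepin at 22°C. The scale (linear intensity) was taken from the values, which were all above 0. Whether the differences in level between arrays were measured, computed or rescaled before deposit stays unknown, so every change below is given on the deposited scale and its direction was also computed after centring the arrays. Centring takes out any change that the probe sets share, whether real or technical. After a centring, rising or falling means relative to the level used for it, and a transcript that falls slowly can then appear to rise.

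The design had been fixed for log2 values, and log2 was taken first because the deposited values were linear. Of 22746 probe sets, 14699 (64.6%) with a mean log2 intensity of at least 5 over all 21 arrays were tested. The 4485 probe sets with a mean under 4 are called background probe sets here. A linear model with 1 mean per group was fitted to all 21 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, which left 14 residual degrees of freedom plus 27.3 from the prior. Its contrasts were the cold effect before the inhibitor (4°C minus 22°C at 0 h), the least-squares slope of log2 intensity over 0, 1 and 3 h at each temperature, and the difference of these slopes (4°C minus 22°C). A half-life is the reciprocal of the rate of fall on the log2 scale, and it holds only on the deposited scale. P-values were adjusted by the Benjamini-Hochberg method, and probe sets with an adjusted p under 0.05 were called; all adjusted p-values of probe sets come from limma. The number of arrays limits the precision. Folds are ratios of geometric means. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

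Probe sets were named through the platform annotation and a reference gene table (assembly TAIR10.1). The annotation gave 1 gene symbol for 13513 probe sets, several for 503 and none for 8730, and 13502 probe sets were matched to 1 locus, 8150 of them among those tested. Genes without a symbol appear by their locus identifier. Of the 290 loci in the gene lists fixed before the data were examined, 42 (14.5%) had a probe set so named, and the remaining loci were not analysed here. Among the genes that were to be named in every comparison, COR15A, COR15B and COR47 had one. Lists with at least 3 tested members were the COR genes, mRNA decay factors, early stress transcription factors, ribosomal proteins, glycolysis and fermentation, reference genes, plastid-encoded and mitochondrion-encoded transcripts. Another 29 gene families were defined from the annotated symbols after the annotation was available and before expression values were examined. The 8 fixed lists and the 29 families were adjusted separately.

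Lists were tested against the other probe sets with limma's camera at a preset correlation of 0.01. Each list was also tested with the correlation estimated, with the replicate number as a block, and with fry, which tests whether the genes of a list move on balance in one direction and compares them with no other gene. A test with cameraPR on the estimates themselves was added after camera had called no fixed list at 22°C. The genes named for each comparison were the 5 with the largest rise and the 5 with the largest fall among called probe sets of 1 locus whose replicates all had that direction, and up to 4 called members of each fixed list with the largest estimates. The members of the added families that are named in the text were chosen after their values were seen.

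The model was tested on simulated data in which 200 of 14699 probe sets were changed. For the cold effect, 74.5% of changes of 0.5 and 99.5% of changes of 1 (log2) were recovered. Slopes of 0.2 per hour were recovered for 88% at 22°C, for 92% at 4°C and for 44% in the difference between temperatures, and slopes of 0.1 per hour for 2%, 1% and 0%. The simulation held no shift of whole arrays and changed far fewer probe sets than were called at 22°C. Its shares therefore do not carry over to the real slopes, some of which were called at sizes below 0.1 per hour. Alternatives were 2 other expression filters, 3 centrings of the arrays (on the array median, on the 4 measured reference genes and, added after the data were seen, on the background probe sets), a block for the replicate number, other sets of time points, a straight line per temperature, an intensity trend in eBayes, fits on the groups of a comparison alone, a stricter threshold, a minimum of 2-fold and leaving out each replicate. Centring on hybridisation or poly-A controls was not run because the values used here held 0 control probe sets, and intron content was not tested because the reference table pairs no loci with exons.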

Results

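Transcript levels were measured in T87 cells of Arabidopsis on 21 arrays, 3 for each of 7 groups. The cells came either from culture at 22°C or from 24 h at 4°C. RNA was taken before (0 h) and at intervals after cordycepin, an adenosine analogue used to block transcription. The fall of a transcript is then taken to follow its decay. Whether the block was equally fast and complete at both temperatures was not tested here, and every slope difference below carries this limit. Some transcripts at 4°C changed little in the first hour and more from 1 to 3 h. A later block in the cold therefore stays open. The series asked how cold changes the stability of mRNA across the genome. The mean intensity of an array at 22°C was 430.2 ± 23.6 (SD, n = 3) at 0 h, 287.1 ± 33.8 at 1 h and 166.2 ± 10.8 at 3 h. At 4°C it was 481 ± 21.3 at 0 h, 469.3 ± 13.4 at 1 h, 467.5 ± 45.2 at 3 h and 396.9 ± 16.7 at 6 h. Background probe sets followed the arrays at 22°C, with median log2 levels of 3.77, 3.25 and 2.46 at 0, 1 and 3 h. Replicates of a group correlated with r between 0.9962 and 0.9989 over all 22746 probe sets.

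**Figure D1:**
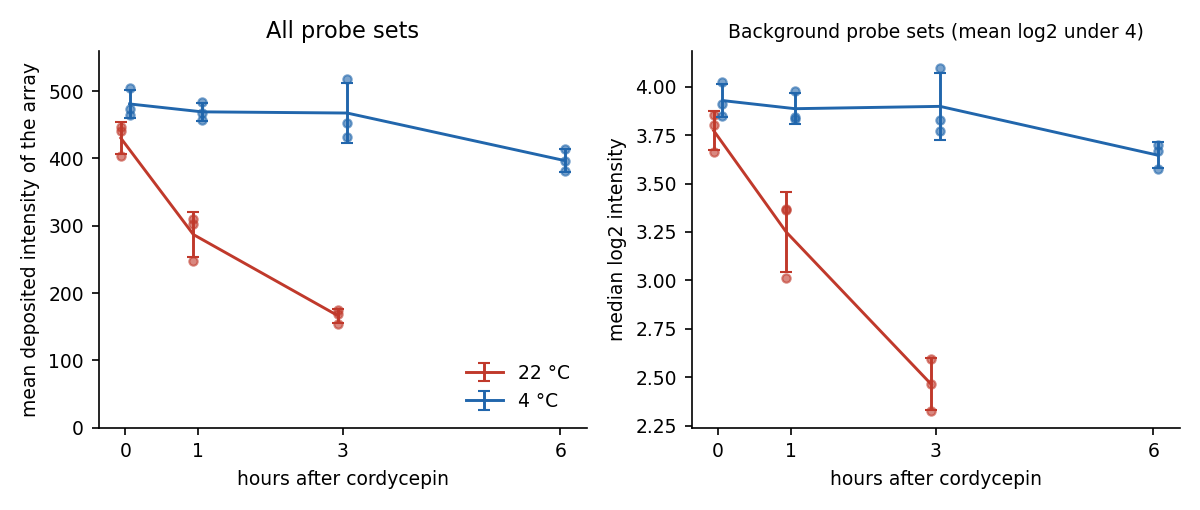
Mean intensity of each array (left, linear scale) and median log2 intensity of its background probe sets (right) against hours after cordycepin at 22°C and 4°C. Points are single arrays and lines with bars are means ± SD of 3 arrays; both measures fell at 22°C, from 430.2 to 166.2 and from 3.77 to 2.46 over 3 h.

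The first comparison set cells after 24 h at 4°C against cells at 22°C, both before cordycepin. The dehydrin gene LTI30 was higher in the cold by a log2 difference of 9.33 ± 0.13 (SE, n = 3 and 3; adjusted p = 2.51e-40), and its mean intensity was 31.4 at 22°C and 19700 at 4°C. COR15B, which encodes a chloroplast protein of freezing tolerance, was higher by 6.80 ± 0.12 (adjusted p = 8.24e-37), the dehydrin gene COR47 by 5.69 ± 0.13 and COR15A by 4.01 ± 0.11. All 6 measured COR genes of the cold regulon were higher, and all 6 also when adjusted over the list alone. The other two, COR27 and COR28, had log2 differences of 3.58 and 2.49. Their median was 4.85, they were higher under each of the 3 centrings, and camera called the list (adjusted p = 4.04e-11; adjusted p = 0.00238 with an estimated correlation). Outside the lists, the largest rises were those of PDF2.1, a plant defensin gene (5.26 ± 0.12), and AT5G39580 (4.13 ± 0.15). At 22°C, LTI30 (mean log2 4.94), COR15A (4.60), COR15B (4.51), AT5G39580 (4.97) and PDF2.1 (4.15) lay under the filter of 5 and COR47 (5.20) just above it, near the background median of 3.77, so their differences give no exact fold. The clock gene GI was 4.39-fold higher (2.13 ± 0.11, adjusted p = 1.24e-20), and the zinc finger factor ZAT10 was 1.01 ± 0.17 higher (adjusted p = 3.12e-06).

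The largest falls in the cold, among probe sets of 1 locus, were those of AT1G54050 (-4.30 ± 0.16, mean intensity 896 at 22°C and 42.8 at 4°C) and of HSP23.5, a small heat shock protein of mitochondria (-3.76 ± 0.12, from 647 to 47.8). AT1G47400 fell by 3.44, from 5850 to 540, AT1G14200 by a log2 difference of -3.27 and AT3G53190 by one of -3.11. These 5 genes and the 5 largest rises were chosen among probe sets whose 3 arrays at 4°C did not overlap the 3 at 22°C. Transcripts encoded in the mitochondrion were lower: 7 of 9 fell, 7 also when adjusted over the list alone, and no centring turned their direction. They were led by the complex I subunit genes nad9 (-1.998 ± 0.154), nad1 (-1.61 ± 0.11), nad5 (-1.23) and nad4L (-1.16), and camera called the list (adjusted p = 0.000122; adjusted p = 0.484 with an estimated correlation). Of 68 plastid-encoded transcripts, 14 rose, 9 fell and 45 were not called on the deposited scale, while 8 were higher and 38 lower after centring on the reference genes. The counts adjusted over the list alone were the same 14 and 9. The large subunit gene of Rubisco, rbcL, rose 4.79-fold (2.26 ± 0.13, mean intensity 182 and 870), and the photosystem II genes psbD (1.78), psbZ (1.56) and psbC (1.35) rose with it. The plastid median was -0.04 and the mean 0.12, and camera gave the downward direction without a call (adjusted p = 0.613).

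Of 10 mRNA decay factors, 7 were higher and 1 lower, also when adjusted over the list alone, but 3 were higher and 2 lower after centring on the reference genes. The exosome helicase gene SKI2 (0.68 ± 0.10), UPF2 of nonsense-mediated decay (0.61) and the decapping activator gene LSM1A (0.52) rose, and RRP6L1 fell (-0.46). Camera did not call this list (adjusted p = 0.613), while fry found a balance towards higher levels (adjusted p = 0.00702). Of the 3 early stress transcription factors, ZAT10 and WRKY6 (0.49) were higher, and WRKY53 had a value of -0.29 (adjusted p = 0.0512) that was called lower when adjusted over the list alone, after each centring and without replicate 1 (-0.27); the list was not called (adjusted p = 0.693). None of 4 ribosomal protein genes passed limma's test, 1 of them at an unadjusted p under 0.05, and 1 of 3 glycolysis and fermentation genes did, lactate dehydrogenase (LDH, 0.56); their adjusted p was 0.693 each, and after centring on the reference genes 4 and 2 of these genes were lower. Of the 4 reference genes, 3 were higher on the deposited scale, and 1 was higher and 1 lower after centring on their own mean (list adjusted p = 0.613). The proteasome gene RPN12A, the only measured member of its list, rose by 0.48. The members named next, of families defined from the annotation, were chosen after their values were seen. The 3 cell wall enzyme genes XTH20 (3.46), XTH18 (1.80) and XTH33 (1.31) were all higher. Of the histone genes 6 of 6 were lower, with HTB2 (-1.003 ± 0.114), HTB4 (-0.98) and HTB11 (-0.70) of the H2B family in front. Both families kept their direction under the 3 centrings. Camera called both families (adjusted p = 0.00694 each; adjusted p = 0.672 and 0.714 with an estimated correlation).

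Over all tested probe sets, 5820 were higher and 3006 lower in the cold, 997 and 457 of them by at least 2-fold. The higher ones made up 65.9% of the calls on the deposited scale, 52.0% (5516 and 5097) after centring on the array median, 48.4% (4988 and 5313) on the background probe sets and 30.6% (3402 and 7734) on the reference genes. These centrings moved the median of all tested probe sets, 0.14 as deposited, by -0.12, -0.16 and -0.32. Relative to that median, LTI30 stood at 9.19, rbcL at 2.12, SKI2 at 0.54, RRP6L1 at -0.59 and nad9 at -2.13.

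**Figure D2:**
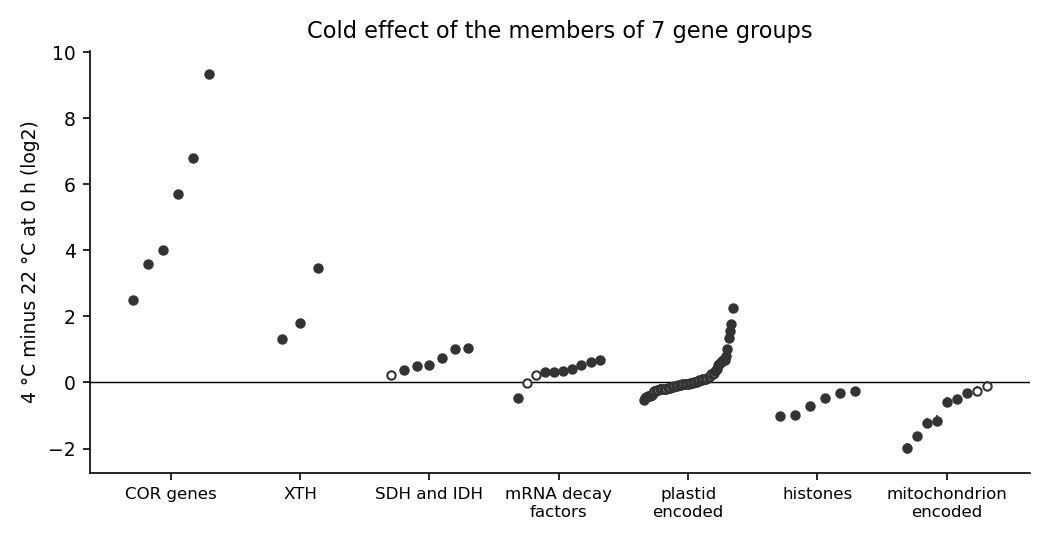
Cold effect (4°C minus 22°C at 0 h, log2, ± SE) of single members of 7 gene groups; filled points passed an adjusted p of 0.05 (limma, 3 arrays against 3). COR and XTH genes lie above 0 and histone and mitochondrion-encoded transcripts below 0 under every centring, while after centring on the reference genes the called mRNA decay factors go from 7 higher and 1 lower to 3 and 2, and the plastid transcripts from 14 and 9 to 8 and 38.

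The second comparison followed transcripts over 0, 1 and 3 h of cordycepin at 22°C. The fastest fall among probe sets of 1 locus was that of AT3G42725, at -1.74 ± 0.04 log2 per hour (SE, n = 3 per time; adjusted p = 3.5e-33), from 522 to 15.1, which on a straight line is a half-life of 0.576 h on the deposited scale. AT5G16250 (-1.69, from 3170 to 96.4), AT3G02640 (-1.59), AT5G45700 (-1.57) and AT3G53650 (-1.57) followed, chosen like it among probe sets whose 3 replicates shared the direction. At 3 h AT5G45700 (mean log2 3.36) and AT3G53650 (3.09) were close to the background median of 2.46, which limits their slopes. AT3G42725, at an intensity of 15.1, was not far above background either. The order of these slopes and the half-life of AT3G42725 are therefore not exact. All 9 mitochondrion-encoded transcripts fell, while after the centrings 5 of them fell and up to 2 rose relative to the array. Among them, nad1 fell at -1.54 ± 0.04 per hour, nad4L at -1.36, nad5 at -1.16 and nad9 at -1.10. All 3 early stress transcription factors fell, under each centring as well: ZAT10 at -1.09 ± 0.06, WRKY6 at -1.06 and WRKY53 at -0.78, which fell from 0 to 1 h and had a rate of 0.04 without a call from 1 to 3 h. Some courses were not straight: ZAT10 stood at 861, 84.3 and 61.9 at 0, 1 and 3 h and nad1 at 1360, 113 and 41.9. The slopes of ZAT10 and nad1 thus average a faster first hour and a slower rest, which need not hold for other transcripts. The mitotic kinase gene AUR1 fell at -1.03 per hour.

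Between these and the slow transcripts stood the mRNA decay factors, of which all 10 fell on the deposited scale and 8 fell and 1 or 2 rose after the centrings. LSM1A (-0.87, half-life 1.14 h), the deadenylase gene CCR4B (-0.84), UPF3 (-0.83) and the exosome gene RRP41 (-0.83) fell fastest among them. All 68 plastid transcripts fell as deposited, but most slowly: 54 lay above the median of all tested probe sets, and 32 to 52 rose and 7 to 14 fell relative to the array under the 3 centrings. The fastest of them were psbZ (-0.90), rps16 (-0.81), matK (-0.78) and psbD (-0.77). All 4 ribosomal protein genes, among them RPL28A (-0.37), all 3 glycolysis and fermentation genes and all 4 reference genes fell as deposited. After the centrings, 1 to 4, 0 to 2 and 1 to 2 of them rose, and up to 1, 1 and 2 fell. Of the 6 COR genes, 5 fell as deposited, with 2 or 3 rising and 2 falling after the centrings: COR28 (-0.71), COR27 (-0.69), COR15B (-0.47), COR15A (-0.42) and COR47 (-0.30). COR15A, COR15B and COR47 started near background at 22°C, and background probe sets fell there at -0.44, so the slopes of these 3 genes there do not measure decay. LTI30 also started near background, but its mean log2 went from 4.94 at 0 h to 5.24 at 3 h. The background median went from 3.77 to 2.46, so LTI30 did not follow it. The sixth, LTI30, rose by 0.09 per hour (adjusted p = 0.0362), and this call was lost without any 1 of the replicates 1, 2 and 3 (0.11, 0.10 and 0.08).

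In some transcripts the level rose after the inhibitor. AT2G03540 rose by 1.29 ± 0.03 per hour, from 44.1 at 0 h to 1240 at 1 h and 1050 at 3 h, and AT5G45180 by 0.96, from 15.8 to 215 and 171. AT2G03390 (0.80), AT4G30470 (0.76) and AT3G60760 (0.72) came next. AT5G45180, AT2G03390 and AT3G60760 started near background, so their rates are not exact. From 1 to 3 h the deposited rate was negative for AT2G03540 (-0.12), AT5G45180 (-0.17), AT2G03390 (-0.03) and AT3G60760 (-0.25), but all 4 lay above the median of all tested probe sets (-0.42), and AT4G30470 went from 42.3 to 70 and 209.

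Over all tested probe sets, 14225 fell and 192 rose at 22°C. The median slope was -0.48 log2 per hour, a half-life of 2.09 h on the deposited scale, and the central 90% of slopes corresponded to half-lives of 1.09 to 7.82 h. Of the probe sets that fell, 3.19% had a half-life under 1 h, 74.5% one of 1 to 3 h and 22.3% a longer one. The background probe sets had a median slope of -0.44, so the fall that all probe sets share cannot be read as decay alone. Centring takes out this shared fall by construction, so the counts after it do not test whether the fall is decay. The centrings moved the median by 0.54 (array median), 0.47 (reference genes) and 0.43 (background probe sets) per hour and gave 7606 rising and 4955 falling probe sets, 5853 and 6385, and 4767 and 7261; the rising share was 1.33% as deposited and 60.6%, 47.8% and 39.6% after them. Relative to the median of all tested probe sets, the medians were -0.61 for mitochondrion-encoded transcripts, -0.58 for early stress factors, -0.17 for mRNA decay factors, 0.04 for ribosomal proteins, 0.07 for glycolysis and fermentation, 0.01 for reference genes, 0.04 for COR genes and 0.12 for plastid transcripts.

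Camera called 0 of the 8 lists at 22°C (1 at an unadjusted p under 0.05), with adjusted p-values from 0.149 for plastid transcripts to 0.817 for ribosomal proteins, and fry called 8. Adjusted over the list alone, the counts of falling and rising members were the same as over all probe sets. For ribosomal proteins, glycolysis and fermentation and reference genes, camera's direction was down although their medians lay above that of the tested probe sets. The cameraPR test on the slopes called the mitochondrion-encoded transcripts (adjusted p = 6.37e-05) and the early stress factors (0.00546) as faster and the plastid transcripts (0.0254) as slower than the rest, while all 3 had adjusted p = 0.902 in camera with an estimated correlation. Among the added families, the 6 histone genes had a median slope of -1.01, and HTB11 (-1.42) and HTB2 (-1.42) fell under each centring; 6 of 6 fell as deposited, and 5 fell and up to 1 rose after the centrings. Camera did not call the family (adjusted p = 0.127) and cameraPR did (adjusted p = 0.000159; adjusted p = 0.984 in camera with an estimated correlation).

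**Figure D3:**
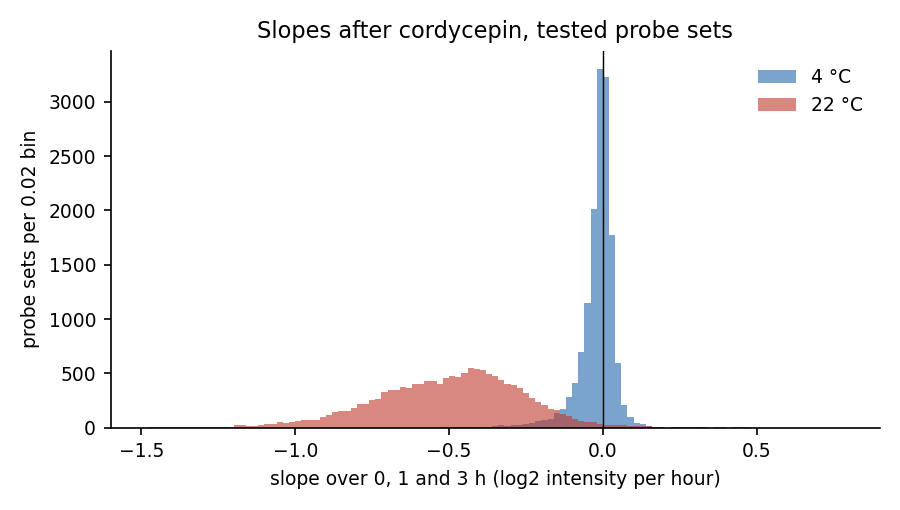
Histograms of the slope of log2 intensity over 0, 1 and 3 h of cordycepin for 14699 probe sets at 22°C and at 4°C, in bins of 0.02 log2 per hour. The medians are -0.48 and -0.01, and the distribution at 22°C is wider.

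The third comparison was the same course after 24 h of cold, with slopes over 0, 1 and 3 h at 4°C. Among probe sets of 1 locus, AT5G63130 fell fastest, at -0.58 ± 0.05 log2 per hour (SE, n = 3 per time; adjusted p = 1.56e-11), from 157 to 48.4 at 3 h, followed by AT1G24530 at -0.54 ± 0.04, from 2220 at 0 h to 2050 at 1 h and 768 at 3 h. AT5G20790 (-0.54), AT4G28240 (-0.52) and AT4G39720 (-0.51) were close behind. All 3 early stress transcription factors fell (3 also when adjusted over the list alone, and 3 under each centring), with ZAT10 at -0.45 ± 0.06 (mean intensity 1640, 1640, 693 and 404 at 0, 1, 3 and 6 h), WRKY53 at -0.37 and WRKY6 at -0.30. Camera called this list (adjusted p = 2.4e-11; adjusted p = 0.00447 with an estimated correlation). IAA29, the only tested member of the auxin-induced Aux/IAA repressors, fell at -0.45 ± 0.04. Some courses at 4°C were slow in the first hour. ZAT10 stood at 1640 at 0 and 1 h, and IAA29 at 328, 315 and 137 at 0, 1 and 3 h. The slopes of ZAT10, IAA29 and AT1G24530 thus average a slow first hour and a faster rest. AT5G63130 (157, 106 and 48.4) and AT4G28240 (146, 97.9 and 48.8) already fell in the first hour. Whether a later block of transcription in the cold made some courses slow was not tested. The ubiquitin ligase genes PUB23 (-0.39), PUB22 (-0.37), ATL5 (-0.35), PUB24 (-0.26) and ATL8 (-0.17) fell as 5 of 9 measured PUB and ATL genes (6 when adjusted over the list alone), 5 under each centring, and camera called this added family (adjusted p = 2.71e-09; adjusted p = 0.399 with an estimated correlation). The members named here were chosen after their values were seen, and ATL8 lost its call without replicate 1 (-0.12).

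Of 68 plastid transcripts, 9 fell at 4°C (10 when adjusted over the list alone; 9 or 10 under the centrings), among them the ribosomal protein gene rps16 (-0.43 ± 0.04), ndhC of the NDH complex (-0.40), psbC (-0.33), psbZ (-0.32) and psbD (-0.28). The list was not called by camera (adjusted p = 0.0635), but it was with the replicate block (0.0413) and by cameraPR (0.0167), and not with an estimated correlation (adjusted p = 0.923). Of the mitochondrion-encoded transcripts 2 of 9 fell, nad1 at -0.25 and nad4L at -0.20 (4 of 9 when adjusted over the list alone, 1 under each centring, which ended the call of nad4L), and camera called the list as lower (adjusted p = 0.00293; adjusted p = 0.81 with an estimated correlation). No COR gene passed limma's test at 4°C, nor at an unadjusted p under 0.05: COR15A had a slope of -0.00 (adjusted p = 0.999), COR15B -0.04, COR47 -0.04 and LTI30 -0.05. Over 0 to 6 h, COR15B (-0.07), COR47 (-0.09) and LTI30 (-0.06) were called as deposited, where the median of all tested probe sets was -0.04 and the centrings moved it by 0.0246 to 0.0654. None of 10 mRNA decay factors, 4 ribosomal protein, 3 glycolysis and fermentation and 4 reference genes passed either (1, 0, 0 and 0 at an unadjusted p under 0.05; list adjusted p = 0.873 for these 4 lists and the COR genes). After centring on the array median, 1 ribosomal protein and 1 reference gene were called as rising, and after the other centrings 1 decay factor as falling. The genes with the largest rise were AT5G01015 (0.56), AT2G03540 (0.55), AT4G02090 (0.47), the glutathione transferase gene GSTU28 (0.43, from 53.6 to 127 at 3 h) and AT1G07300 (0.38). AT2G03540 stood at 101, 112, 300 and 657 at 0, 1, 3 and 6 h, so it too was slow in the first hour. For the added family, 1 of 3 GSTU genes rose, also under each centring, and camera called it (adjusted p = 0.0184; adjusted p = 0.537 with an estimated correlation).

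Over all tested probe sets, 797 fell and 104 rose at 4°C over 0 to 3 h, with a median slope of -0.01. Without replicates 1 and 2 in turn, 473 and 505 fell, and without replicates 1, 2 and 3, 169, 61 and 50 rose. A straight line per temperature, whose residual spread takes in the bend of the courses at 22°C, called 52 and 5, and of the named genes that had passed at 4°C only AT5G63130, AT5G20790, AT4G39720, ATL5, rps16 and ndhC passed it. The rising share of calls was 11.5% as deposited, 69.3% (2256 rising, 1000 falling) after centring on the array median, 18.1% (348 and 1578) on the reference genes and 21.5% (349 and 1272) on the background probe sets. With the course extended to 6 h, 7363 fell and 271 rose as deposited, 2525 and 7826 after centring on the array median, 5705 and 1317 on the reference genes and 3528 and 3515 on the background probe sets.

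**Figure D4:**
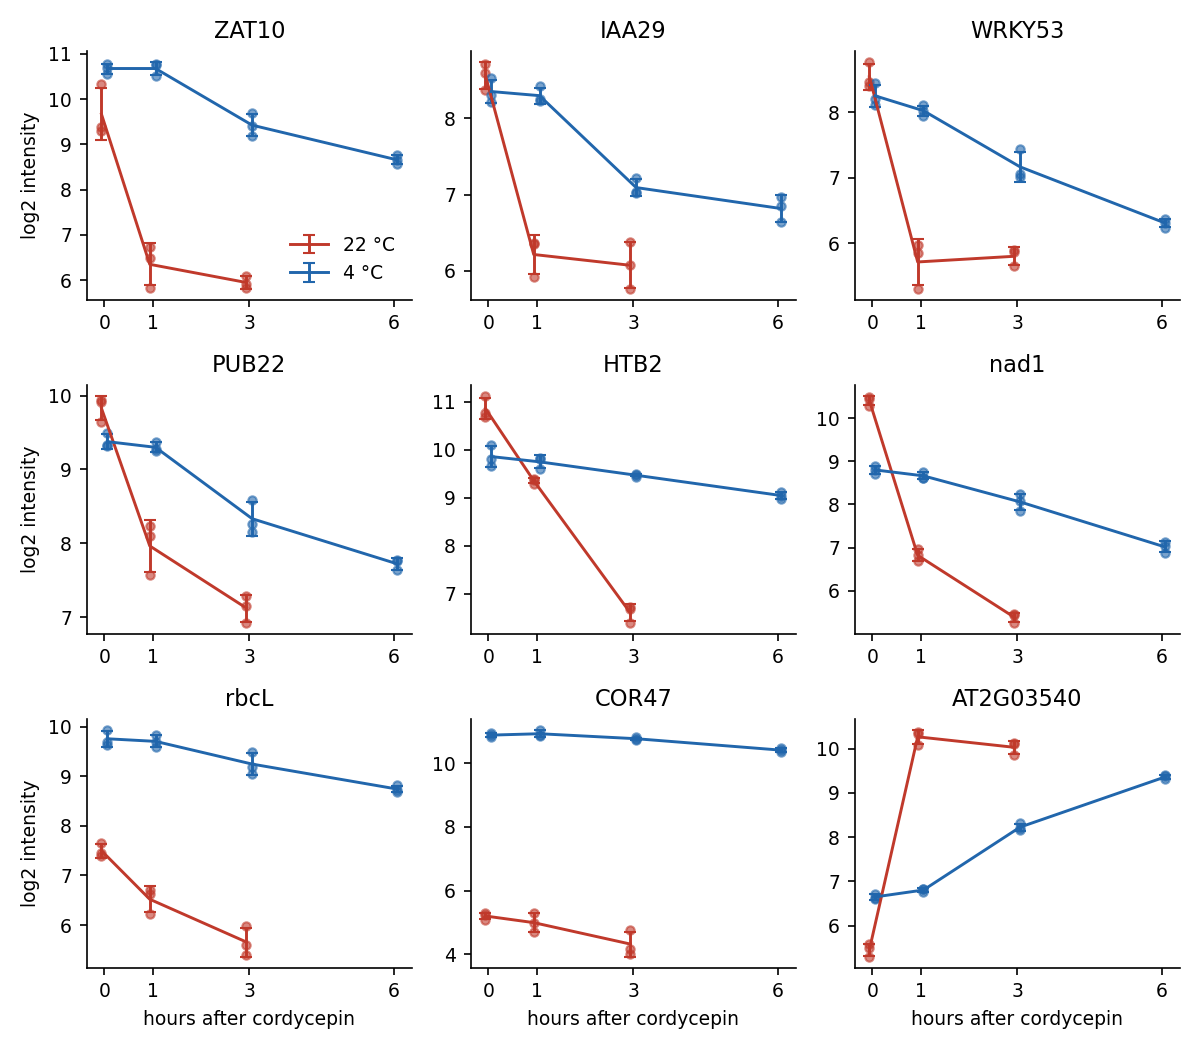
Log2 intensity against hours after cordycepin at 22°C and 4°C for ZAT10, IAA29, WRKY53, PUB22, HTB2, nad1, rbcL, COR47 and AT2G03540, on the deposited scale; points are arrays and lines join means of 3 arrays. ZAT10 fell at both temperatures (-1.09 and -0.45 log2 per hour over 0 to 3 h), COR47, near background at 22°C, had a slope of -0.04 without a call at 4°C, and AT2G03540 rose at both.

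The fourth comparison tested the difference between the slopes, 4°C minus 22°C, where a value above 0 means a slower fall or faster rise in the cold. The largest differences belonged to AT3G42725 (1.69 ± 0.06 log2 per hour, adjusted p = 1.64e-26), AT5G16250 (1.60), AT3G02640 (1.495), AT3G59850 (1.46) and AT5G45700 (1.43). All 9 mitochondrion-encoded transcripts had a difference above 0, led by nad1 (1.28 ± 0.05) and nad4L (1.16), with 5 above 0 and 0 below after each centring. All 10 mRNA decay factors did too, LSM1A by 0.88, RRP41 by 0.81, CCR4B by 0.81 and UPF3 by 0.75, with 8 above 0 and 1 or 2 below after the centrings. AUR1 had a difference of 0.96, WRKY6 one of 0.75 and ZAT10 one of 0.64, which ended as a call after centring on the array median (0.14) or the reference genes (0.17). All 3 early stress factors were above 0 as deposited, and 1 or 2 above and up to 1 below after the centrings. In the histone family HTB11 (1.35) and HTB2 (1.28) led 6 of 6 genes above 0, with 5 above and up to 1 below after the centrings (camera adjusted p = 0.0671).

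Of the plastid transcripts, 64 of 68 had a slope difference above 0 as deposited, and 2 to 7 were above and 24 to 44 below after the centrings. The largest were those of matK (0.76) and petB (0.61). With a median of 0.35, 57 of them lay below the median of all tested probe sets, and camera called the list as lower than the rest (adjusted p = 0.00126; adjusted p = 0.89 with an estimated correlation). For ndhC the slopes at the 2 temperatures were not told apart (difference 0.06, adjusted p = 0.353), and for ATL5 the difference was 0.08 (adjusted p = 0.227; 0.14 and called without replicate 2). Both turned below 0 and were called after each centring. Of the COR genes 5 had a difference above 0 as deposited, with 2 above and 2 or 3 below after the centrings. Among them were COR27 (0.70), COR15B (0.43), COR15A (0.41) and COR47 (0.26), of which COR15A and COR47 turned below 0 under each centring; those of COR15A, COR15B and COR47 rest on levels near background at 22°C and measure no change of decay. LTI30, near background at 22°C only at the start, had a difference of -0.14, whose call was lost without replicate 1 (-0.14). IAA29 had a difference of 0.28 that turned below 0 after each centring. All 4 ribosomal protein, 3 glycolysis and fermentation and 4 reference genes were above 0 as deposited; after the centrings 0, 1 and 1 to 2 were above and up to 3, 2 and 2 below. No list besides the plastid transcripts was called by camera (adjusted p = 0.127 for mRNA decay factors, 0.352 for mitochondrion-encoded transcripts and COR genes, and 0.796 for the remaining 4 lists), and adjustment over the list alone changed no count. The largest differences below 0 among probe sets of 1 locus were those of AT5G45180 (-0.93), AT2G03540 (-0.74), AT2G03390 (-0.73), AT1G29680 (-0.67) and AT3G60760 (-0.65); all but AT2G03540 started near background, so their sizes are not exact.

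Over all tested probe sets, 14096 slope differences were above 0 and 130 below, with a median of 0.46. Of the 14096, 14064 fell at 22°C, 13285 of these without a call at 4°C and 736 with a fall at both temperatures. Of the 130, 116 rose at 22°C. The share above 0 was 99.1% of calls as deposited, 41.6% (4729 above and 6627 below) after centring on the array median, 50.0% (5531 and 5524) on the reference genes and 60.8% (6474 and 4171) on the background probe sets, which moved the median by -0.51, -0.47 and -0.42. Centring takes out the part of the difference that the probe sets share, so the counts after it do not test that part. How far the shared part of the difference is decay rests on the unknown basis of the array levels. It also rests on an equal block of transcription at both temperatures, which was not tested.

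The spread of slopes between transcripts does not depend on the level of an array, and it was compared next. Across probe sets, the SD of slopes free of noise was 0.254 log2 per hour at 22°C and 0.0613 at 4°C, a ratio of 4.14. Among background probe sets the SD of slopes was also larger at 22°C (0.0709) than at 4°C (0.0279), so the wider spread need not be decay alone. The SDs of single replicates averaged 0.259 and 0.0715 (n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 values can give), and the medians of their slopes were -0.51, -0.45 and -0.47 at 22°C and -0.07, -0.01 and 0.05 at 4°C (exact permutation p = 0.1). Transcripts that fell fast at 22°C were over-represented among those that fell at 4°C: 297 of the 797 belonged to the 1469 fastest at 22°C, where 79.7 would be drawn by chance (Fisher's exact p = 3.91e-102). Of the 104 that rose at 4°C, 73 belonged to the 1470 slowest at 22°C (10.4 by chance) and 48 also rose at 22°C (1.36 by chance). Slopes at the 2 temperatures correlated across probe sets with r = 0.407 and rho = 0.395; probe sets are not independent replicates.

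The last comparison set the cold effect on the level of a transcript against the change of its decay. Computed from arrays that share no sample (0 h arrays for the cold effect, 1 to 3 h rates for decay), the correlation across 14699 probe sets was r = -0.0704 (rho = -0.0513), and -0.0592, -0.0764 and -0.069 in single replicates. The 1 to 3 h rates leave out the first hour, in which some transcripts had already fallen at 22°C. For these the rates need not follow the change of decay. From 1 to 3 h in replicate 2, ZAT10 went from 6.73 to 6.10 (log2) at 22°C and from 10.74 to 9.395 at 4°C. Its slope difference over 0, 1 and 3 h was nevertheless above 0. Between different replicate numbers the correlation was -0.116 with slopes over 0, 1 and 3 h. With slopes that share the 0 h arrays it was -0.128, where simulated unchanged groups gave -0.618; the covariances were -0.0199 and, simulated, -0.00379. In the 1470 probe sets with the lowest cold effects (median -0.80), the median difference in rate was 0.46 log2 per hour, and in the 1470 with the highest (1.16) it was 0.39; in the 8 sets between it went up and down between 0.40 and 0.42. Of the 130 probe sets with a slope difference below 0, 80 were higher after cold (51.5 by chance) and 9 lower (26.6 by chance). After centring on the array median, 2484 of the 6627 below 0 were higher (2487 by chance) and 2130 lower (2298 by chance). Of the 4729 above 0 after this centring, 1769 were higher (1775 by chance) and 1874 lower (1640 by chance). These counts share the 0 h arrays.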

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

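The tests of the fall of the arrays as a whole, of the rise at both temperatures and against a factor per array, and of the plastid transcripts were chosen only after those results were seen; the counts of other splits and the tests on shared probe sets and neighbouring loci were set before.

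Slopes differed between the 2 temperatures for most transcripts: 14096 probe sets had a slope difference above 0 on the deposited scale and 130 one below 0. Among them, 46 were called in opposite directions at 22°C and 4°C with a called difference as deposited, and 11 to 16 of these 46 were so called after the 3 centrings. AT5G10695 was one of the 46 as deposited, falling at -0.81 log2 per hour at 22°C and rising at 0.25 at 4°C (difference 1.06); its rise at 4°C was not called with a straight line per temperature. The plastid-encoded transcripts differed as a list (camera adjusted p = 0.00126; adjusted p = 0.89 with an estimated correlation). The change from 3 to 6 h at 4°C was not a comparison of its own; 5770 probe sets were lower at 6 h than at 3 h at 4°C and 133 were higher on the deposited scale; after centring it was 1617 lower and 3566 higher (array median), 3940 and 405 (reference genes) and 1797 and 1098 (background probe sets).

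Other splits of the arrays were counted for each comparison. For the cold effect, 10 splits are too few for a share under 0.05; the real split, 1 of them, called 8826 probe sets and the highest other 0. For decay at 22°C, 1 of 100 regroupings, the real one, called as many as 14417 probe sets (highest other 13795). For decay at 4°C it was 1 of 100 (901, highest other 806), and for the slope difference 1 of 100 (14226, highest other 13486). In these 3 the real grouping called the most probe sets, and 1 of 100 is the smallest share that such draws can give. Some regroupings came close to the real count, and the replicates may be technical. Chance is thus made less likely as the source of these counts but is not excluded. At 22°C and for the slope difference the counts also follow the fall of the arrays as a whole. The regroupings there do not test changes of single transcripts.

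The arrays at 22°C fell as a whole after cordycepin. A factor per array, set before deposit, is 1 candidate explanation, since background probe sets fell with a median slope of -0.44 log2 per hour, close to that of the tested ones. Such a factor cannot make the slopes of probe sets differ, and these spread 4.14 times as widely at 22°C as at 4°C. Slopes of background probe sets also spread more widely at 22°C (SD 0.0709) than at 4°C (0.0279). The wider spread therefore need not come from decay alone. Loss of mRNA per cell stays open, because the values used here held 0 external control probe sets.

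Some transcripts rose at 22°C after an inhibitor of transcription. Of the 192, 48 also rose on the separate arrays at 4°C, where 1.36 would by chance, which argues against spread between arrays. A factor per array could only make transcripts rise if it raised the later arrays, and background probe sets fell, with a median slope of -0.44. Probe sets shared by several genes made up 4.69% of them and 3.85% of the others (Fisher's exact p = 0.568), which argues against these as the source. Of 118 rising loci, 4 had a rising neighbour, against a mean of 3.43 in 10000 random draws (permutation p = 0.51); this does not decide whether neighbouring loci rose together, and no biological explanation was tested.

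Plastid transcripts that were higher after cold fell at 4°C more often than others: of 14 and 9, 8 were both (1.85 by chance, Fisher's exact p = 3.33e-06). Both calls use the 0 h arrays at 4°C. These arrays as the only source are argued against by values that share no array. The cold effect and the rate from 1 to 3 h at 4°C correlated across the 68 genes with r = -0.696 (permutation p = 1e-05, the smallest it can give). By rank the correlation was weaker, with rho = -0.266 (permutation p = 0.03). Plastid genes that are transcribed together are not independent, so the p-values of this paragraph are likely too small. Without the 5 genes farthest in cold effect r was -0.418, and with the rates at 22°C it was -0.196 (permutation p = 0.11). A change of plastid RNA as a whole is argued against by the SD of the cold effect across these genes, 0.51 log2 free of noise. No biological explanation was tested, and temperature and light differ together.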

How the results depend on the processing

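Centring on background probe sets, centring of the course to 6 h, cameraPR and the single intervals of 0 to 1 h and 1 to 3 h at 22°C were tests chosen only after results were seen. Of 2414 alternatives run on 164 results of a single gene or list, 2277 gave the same direction and the same side of the threshold, 64 ended a call, 26 added one and 47 reversed a direction, 40 of the 47 under a centring. Of 158 run on 14 counts or values that answer a comparison, 102 left them within the limits set and 56 moved them.

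Centring on background probe sets, on the array median and on the reference genes gave, in this order, 5313, 5097 and 7734 probe sets lower in the cold, and on the reference genes 3402 higher. At 22°C 4767, 7606 and 5853 rose and 7261, 4955 and 6385 fell. At 4°C 349, 2256 and 348 rose, and 1272 (background) and 1578 (reference) fell. Slope differences above 0 numbered 6474, 4729 and 5531, and below 0 4171, 6627 and 5524.

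In the same order, slopes at 22°C turned positive for COR15A (0.0148, 0.124, 0.0554), COR47 (0.13, 0.24, 0.17), RPL28A (0.0555, 0.164, 0.0961), LSM3A (0.29, 0.40, 0.33), LSM3B (0.19, 0.30, 0.235), LSM6A (0.21, 0.32, 0.25) and LSM6B (0.29, 0.40, 0.33), and for COR15B on the array median (0.0684) and reference genes (0.0001216). Slope differences turned negative for ATL5 (-0.35, -0.43, -0.39), COR15A (-0.0112, -0.0964, -0.058), COR47 (-0.17, -0.25, -0.21), IAA29 (-0.15, -0.23, -0.19) and ndhC (-0.37, -0.45, -0.41), and for COR15B on the last 2 (-0.0749, -0.0366). These turns under a centring are relative to the level used for it. From 0 to 1 h LSM3A (0.13) and LSM6B (0.00175) turned positive as deposited. From 1 to 3 h AT2G03390 (-0.032), AT2G03540 (-0.12), AT3G60760 (-0.25) and AT5G45180 (-0.17) turned negative as deposited and WRKY53 (0.0433) positive.

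In the cold, 997 probe sets were higher and 457 lower by at least 2-fold. At 22°C, 384 rose from 0 to 1 h and 127 from 1 to 3 h, 111 with a filter of at least 6, and 22080 fell with no filter. At 4°C, 271 rose and 7363 fell over 0 to 6 h, 65 rose at an adjusted p under 0.01, 172 rose in a fit of the groups of the comparison alone, and a straight line per temperature left 5 and 52. With no filter 21914 slope differences were above 0, and 69 (filter of at least 6) and 84 (straight line) were below. The ratio of spreads was 4.27 with a filter of at least 6 and 4.22 with none. The relation of cold effect and decay was r = -0.128 with shared 0 h arrays and -0.116 between different replicate numbers.

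Of the 8 fixed lists, camera with an estimated correlation called 1 in the cold, 1 at 4°C and 0 for the slope difference, where camera at the preset correlation called 1 (2 lists had an unadjusted p under 0.05). Fry called 5 in the cold, 8 at 22°C, 1 at 4°C and 8 for the slope difference, and cameraPR 3 at 22°C and 2 for the slope difference. Most ended calls of single genes or lists came from the straight line (25), the minimum of 2-fold (10) and the estimated correlation (8).

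Without 1 replicate number or, for the cold effect, also without 1 array, 4391 to 5779 probe sets were higher and 2325 to 3065 lower in the cold, 153 to 217 rose and 14142 to 14169 fell at 22°C, 50 to 169 rose and 473 to 977 fell at 4°C, and 13764 to 14109 slope differences were above 0 and 97 to 131 below. The relation of cold effect and decay ranged from -0.0756 to -0.0658 and the ratio of spreads from 4.005 to 4.33.

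Replicate numbers do not pair the arrays by the labels. Residuals of 63 pairs with the same number correlated with a median r of 0.101 (-0.0711 to 0.37; -0.0456 for other pairs), and 18 of 21 arrays were closest to their own number. With the number as a block, 6106 were higher and 3160 lower in the cold, 205 rose and 14241 fell at 22°C, 142 rose and 976 fell at 4°C, and 14140 slope differences were above 0 and 139 below; camera then called 2, 0, 3 and 1 of the fixed lists. Centring on hybridisation controls and on poly-A controls, and 2 tests of intron content, were not run.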

Other observations

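The genes and tests described here were chosen only after the results were seen. Within the LSM family, slopes at 22°C were unequal. LSM1A fell at -0.87 log2 per hour and LSM1B at -0.59, while LSM3A (-0.14), LSM3B (-0.24), LSM6A (-0.22) and LSM6B (-0.14) fell slowly as deposited and rose under each centring. The split was made after the values were seen, and the family was not called (camera adjusted p = 0.624; adjusted p = 0.984 with an estimated correlation; cameraPR 0.541). LSM1 is found only in the decapping complex of the cytoplasm, and the other 2 subunits also in that of the spliceosome. In the cold before cordycepin, 6 of 7 genes of succinate and isocitrate dehydrogenase were higher as deposited and 5 or 6 after the centrings, with none lower. SDH1-1 rose by 1.03 (from 1660 to 3400), SDH2-1 by 1.01 and SDH2-2 by 0.74, and the family was not called by camera (adjusted p = 0.075). Of 6 beta-glucosidase genes 5 were higher, also after the centrings, where BGLU44 was lower. BGLU15 (1.12, from 1730 to 3760) and BGLU46 (1.06) rose most (camera adjusted p = 0.075).

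At 4°C, AT1G47400 fell by 1.90 ± 0.11 from 3 to 6 h (297 to 79.1), AT2G41410 by 1.36 and nad4L by 1.23. AT5G45180, which rose within 1 h at 22°C, rose at 4°C only after 3 h (from 21.6 to 130), and AT1G29680 likewise (from 24.3 to 65.9); both started near background, so the size of the rise is not exact. AT2G03130 (1.82) and ARPN (1.72, from 145 to 474) rose as well.

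Of the 8 plastid genes that fell at 4°C and were higher after cold, 6 belong to 2 sets that are transcribed together, psbD, psbC and psbZ, and ndhC with its neighbours ndhJ and ndhK, so the 68 genes are fewer independent transcripts than their number.

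The transcripts that rose at 22°C rose in the first hour as deposited: 161 of 192 were called from 0 to 1 h. From 1 to 3 h, 48 rose and 70 fell as deposited, and 151 to 161 rose and 4 to 9 fell after the 3 centrings. Their median log2 level at 0 h was 5.53, against 8.002 for all tested probe sets, and 114 of them were higher and 18 lower after cold. Over all tested probe sets, 39.59% were higher and 20.45% lower. The rise at 22°C and the cold effect share the 0 h arrays at 22°C, so these counts lean towards higher ones by construction.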
